A study of Homo sapiens with 22 samples.

How the data were processed

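Total RNA (200 ng per sample) from JHOC9 and JHOC5 cells infected with NT, SPINK1 or IL-6 knockdown virus was labelled with biotin and hybridised to the GeneChip Human Transcriptome Array 2.0, per the labels. RMA, a method that corrects background, normalizes across arrays and summarises probes, is named in the submitters' processing notes without a version. Its software, the annotation and the genome build are not given in the sources used here. The series matrix holds deposited log2 values, which equal the log2 signal of each cluster minus its median over the 22 arrays within 2.06e-06. The other deposited table holds the same log2 values, within 5.00e-07, and linear intensity values from 2.81 to 15242 that its header calls raw. These deposited intensity values are summarised per cluster and have nearly the same distribution on each array, with sorted log2 values within 0.423 of each other, so they are not scanner values. Because RMA brings all arrays to a common distribution, an overall shift in RNA content between groups would not appear in these values.

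Groups were taken from the sample titles. All 22 arrays entered 1 model with 6 group means in limma 3.58.1 under R 4.3.3, and contrasts were tested two-sided with eBayes and Benjamini-Hochberg adjustment at 0.05 over 65526 clusters. The model has 16 residual degrees of freedom, plus 4.22 from the prior. Counts at an unadjusted p under 0.05 are to be read against the share of 0.05 of clusters that chance alone would give. Tables were read with version 1.17.8 of the data.table package, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. A change is the difference of log2 group means, its SE is the moderated one, and SDs are over the arrays of a group. The 9 contrasts were each knockdown against NT in each line, the difference of each knockdown effect between lines, the knockdowns against each other in each line, and NT against NT. The designs, the rule for named items and most alternatives were fixed before the data were examined.

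The plan assumed 1 probe set per named gene. The files do not pair IDs with names, so all clusters were tested, and 25 preset gene lists, the levels of SPINK1 and IL-6, and marker levels were not analysed here. The rule for named items was the largest changes in each direction with an adjusted p under 0.05 and all knockdown arrays outside the range of the NT arrays. It was limited to 2 rises and 2 falls for each knockdown against NT, since the items have no names. All 55 clusters called with the SPINK1 virus in JHOC9 and all 159 called with the IL-6 virus in JHOC9 met that range condition. In JHOC5, 4031 and 879 called clusters met it for SPINK1 and IL-6. Chance puts 3.57% of clusters outside the range in either direction, and over all clusters the share was 3.60% and 15.4% for SPINK1 in JHOC9 and JHOC5, and 6.20% and 7.52% for IL-6. Called clusters were chosen for differing, so their separation is no independent evidence. Values that agree within 1e-05 on all arrays mark 1034 clusters that repeat another, and 64492 are distinct.

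Arrays of different groups share replicate letters in the titles, which tie the letters to Experiments A to E for the NT arrays only. Deviations from the group means of same-lettered NT and SPINK1 knockdown arrays in JHOC9 correlated at 0.43, 0.32 and 0.20. All lay above 0.1, so this comparison was treated as paired and its blocked count is printed beside it. SPINK1 knockdown replicate c correlated more with an NT array of another letter, at 0.435, so the pairing is uncertain. The main counts and overlaps come from the fit without the block. The other comparisons each had a pair under 0.1 and were not treated as paired.

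On simulated data with the spread of the real clusters, log2 changes of 0.5 were recovered for 67.6% of changed clusters in the JHOC9 SPINK1 comparison, 75.4% in the JHOC5 SPINK1 comparison, 70.3% in the JHOC9 IL-6 comparison and 69.5% in the JHOC5 IL-6 comparison, each over 65526 clusters. Changes of 0.25 were recovered for 7.84%, 9.84%, 12.3% and 5.56% in the same order.

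Alternatives covered the replicate block, fewer arrays in the fit, a filter on dim clusters (above the array median in at least 3 arrays), other normalizations, the other table, eBayes with trend and robust, array weights, stricter thresholds, and each array left out. Numbers of settings in which a named cluster lost its call leave out the stricter thresholds. Cyclic loess, counting repeated clusters once, and a letter block shared by the lines for the NT contrast were chosen after seeing the data. Grouping clusters by the chromosome code in their IDs was too. The code is the pair of characters after TC, following the array maker's naming. Clusters per code and RefSeq genes per chromosome correlated at a Spearman's rho of 0.969 over 25 codes, and the codes were tested with camera.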

Results

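JHOC9 and JHOC5 are established cell lines of ovarian clear cell carcinoma. Cells plated in 35 mm dishes were infected with an NT control lentivirus, a lentivirus against SPINK1, which encodes a secreted trypsin inhibitor, or a lentivirus against IL-6, an inflammatory cytokine. The 22 arrays fall into 6 groups. Each line has 5 NT arrays, 3 SPINK1 knockdown arrays and 3 IL-6 knockdown arrays, with 1 virus per target gene. JHOC9 was grown in 20% serum and JHOC5 in 10% serum, so serum and line differ together. Each array measured 65526 transcript clusters, the array's units for a transcribed region. The median log2 signal per array lay between 4.78 and 4.95, and the median SD of a cluster within a group lay between 0.091 and 0.117 on the log2 scale. The number of arrays limits the precision. The titles place the 5 NT arrays of each line in Experiments A to E and give the knockdown arrays a replicate letter only. They do not say whether the knockdown arrays came from separate cultures, so p-values measure the spread between these arrays, which may be technical in part. The files do not pair cluster IDs with gene names, so the levels of SPINK1 and IL-6 themselves were not analysed here, and clusters are given by their IDs.

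The first question was what the SPINK1 virus changed in each line. In JHOC5, 4284 clusters changed, of which 1753 were higher and 2531 lower than with NT. Of these, 19 rose and 269 fell at least 2-fold. The largest falls were in TC01002412.hg.1, with a log2 change of -2.51 ± 0.15 (SE, 3 against 5 arrays), and in TC04002654.hg.1, with -2.16 ± 0.16. The largest rises were in TC01001685.hg.1, 1.68 ± 0.11, and in TC08001051.hg.1, 1.47 ± 0.12. TC01002412.hg.1 went from 9.39 ± 0.36 (SD, n = 5) with NT to 6.87 ± 0.05 (SD, n = 3) on the log2 signal scale, with a limma adjusted p of 1.65e-09. Centring each array on its median gave 1109 higher and 2672 lower clusters. The count was 2771 without SPINK1 knockdown replicate d and 2624 without replicate e. Array weights raised it to 7047, with 3631 higher and 3416 lower, so the excess of falls depends on the weighting.

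In JHOC9 the SPINK1 virus changed 55 clusters, 9 higher and 46 lower. An unadjusted limma p under 0.05 was found for 3243 of the 65526 clusters, near the share of 0.05 that chance alone would give. The largest falls were in TC04001745.hg.1, with a log2 change of -1.02 ± 0.13 (SE, 3 against 5 arrays), and in TC19000416.hg.1, with -0.93 ± 0.09. Both clusters also fell in JHOC5, with log2 changes of -1.53 and -1.70. The largest rises were in TC20000928.hg.1, 0.58 ± 0.09, which also rose by 0.56 in JHOC5, and in TC15002759.hg.1, 0.50 ± 0.09, whose JHOC5 change was 0.04 with a limma adjusted p of 0.873. The JHOC9 call of TC15002759.hg.1 was lost in 10 of 20 alternative settings, with a limma adjusted p of up to 0.391, that of TC20000928.hg.1 in 4 and that of TC04001745.hg.1 in 2. With the replicate letter as a block, which pairs the arrays of this comparison, 120 clusters passed, 28 higher and 92 lower. The count was 12 with the compared groups alone, 19 with JHOC9 arrays alone, 29 with arrays centred on their median and 36 after cyclic loess. With array weights it was 2948, where 1419 were higher and 1529 lower. In that fit SPINK1 knockdown replicate b had a weight of 6.46, against 0.594 and 0.419 for replicates a and c. The count was 36, 34 and 35 without NT replicates a, b and e, and 25 and 27 without SPINK1 knockdown replicates a and b. Without replicate c it was 44, of which 23 were higher.

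**Figure D1:**
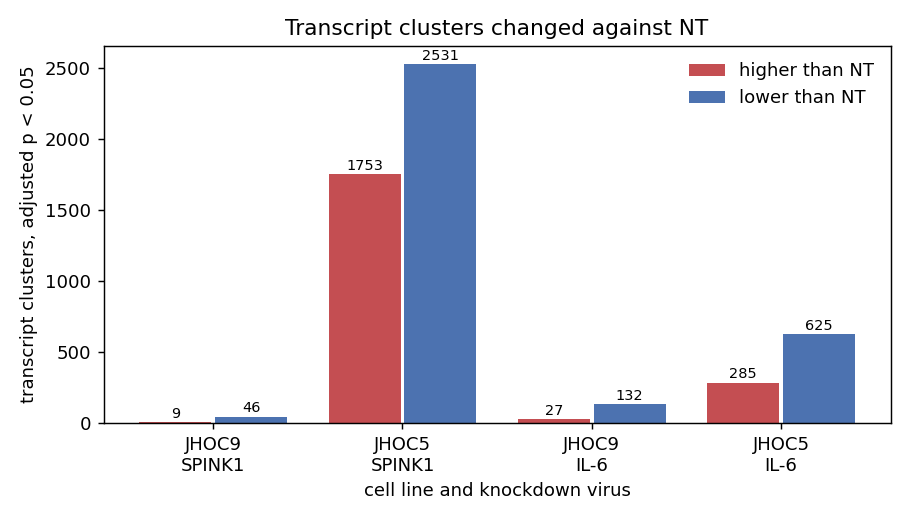
Number of transcript clusters higher (red) and lower (blue) than with the NT virus at a limma adjusted p under 0.05, for each cell line and knockdown virus (3 knockdown against 5 NT arrays each). The bars run from 9 higher clusters with the SPINK1 virus in JHOC9 to 2531 lower clusters with the same virus in JHOC5.

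The next comparison asked whether the SPINK1 virus acted differently in the 2 lines. The change differed between the lines for 813 clusters. Of these, 673 fell further in JHOC5 and 140 rose further in JHOC5, and none was called in opposite directions in the lines. Among the 813 clusters, 806 were also called in JHOC5 and 27 in JHOC9, and the median absolute log2 change was 0.76 in JHOC5 and 0.15 in JHOC9. Over the 4284 clusters called in JHOC5, the median ratio of the JHOC9 to the JHOC5 change was 0.207. With the replicate block, 1151 clusters passed, 906 with a positive and 245 with a negative difference (JHOC9 minus JHOC5). The count of 813 fell to 539 and 449 without JHOC9 SPINK1 knockdown replicates a and b. It fell to 442 without JHOC5 SPINK1 knockdown replicate d or e. Array weights raised it to 3621, with 2047 positive and 1574 negative differences (JHOC9 minus JHOC5), against 673 and 140 without weights.

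Of the 46 clusters that the SPINK1 virus lowered in JHOC9, 43 were among the 2531 that it lowered in JHOC5, against 1.78 for independent lists (Fisher's exact test, two-sided, p = 1.65e-57, over clusters, which are not independent of each other). Of the 9 higher in JHOC9, 6 were also higher in JHOC5. No array enters the changes of both comparisons, but the calls in both lines use 1 spread per cluster, estimated from all arrays. A cluster whose spread was estimated too low could be called in both. The overlap between lines was not computed with separate fits. The median log2 change of the 43 shared falls was -0.47 in JHOC9 and -0.94 in JHOC5, and 39 of them fell further in JHOC5. Across all clusters the changes in the lines correlated at r = 0.31, and at 0.20 without JHOC9 SPINK1 knockdown replicate c. The 49 calls shared in direction were 90 with the replicate block, 27 with arrays centred on their median and 796 with array weights. They were 32 and 29 without JHOC9 NT replicates a and b, and 23, 24 and 26 without JHOC9 SPINK1 knockdown replicates a, b and c.

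The IL-6 virus changed 910 clusters in JHOC5, 285 higher and 625 lower than with NT. The largest falls were in TC09000323.hg.1, with a log2 change of -1.36 ± 0.27 (SE, 3 against 5 arrays), and in TC01004414.hg.1, with -1.36 ± 0.16. The largest rises were in TC08001062.hg.1, 1.31 ± 0.13, and in TC12003230.hg.1, 1.30 ± 0.10. Of the 910 clusters, 6 rose and 25 fell at least 2-fold. The call of TC09000323.hg.1 was lost in 4 alternative settings, with a limma adjusted p of up to 0.0735. The count was 447 with the compared groups alone and 595 without NT replicate d. It was 510 without IL-6 knockdown replicate a, where 249 were higher and 261 lower. Array weights raised it to 3369, with 1783 higher and 1586 lower, which turns the direction that held more clusters. In that fit IL-6 knockdown replicate b had a weight of 3.28, against 0.319 and 0.757 for replicates a and c.

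In JHOC9 the IL-6 virus changed 159 clusters, 27 higher and 132 lower. The largest falls were in TC04002368.hg.1, with a log2 change of -1.10 ± 0.13 (SE, 3 against 5 arrays), and in TC07000113.hg.1, with -0.87 ± 0.14. The largest rises were in TC17000279.hg.1, 0.70 ± 0.15, and in TC15001529.hg.1, 0.66 ± 0.13. These rises lay close to the threshold, with limma adjusted p of 0.0473 and 0.0349, and their calls were lost in 14 and 12 of 19 alternative settings. Their mean log2 signals with NT were 3.61 and 2.52, below the array medians of 4.78 to 4.95, and the filter on dim clusters removed both. That filter left 14 higher and 158 lower clusters in this comparison. The call of TC07000113.hg.1 was lost in 4 of 20, with a limma adjusted p of up to 0.236, among them the fits without IL-6 knockdown replicate b (0.0812) or e (0.0832). The count was 2 with the compared groups alone and 33 with JHOC9 arrays alone. It was 65, 72 and 64 without NT replicates a, b and c, and 70, 255 and 24 without IL-6 knockdown replicates b, d and e. Without IL-6 knockdown replicate b, 25 were higher and 45 lower, and without NT replicate b, 5 were higher and 67 lower. Array weights gave 63 higher and 141 lower.

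Of the 132 clusters that the IL-6 virus lowered in JHOC9, 87 were also lower in JHOC5, against 1.26 for independent lists (Fisher's exact test, two-sided, p = 9.94e-144, over clusters). No cluster was higher in both lines, where independent lists would share 0.117. These lists too use the same spread per cluster. The median log2 change of the 87 shared falls was -0.45 in JHOC9 and -0.65 in JHOC5. The shared calls were 47, 51 and 43 without JHOC9 NT replicates a, b and c, and 37, 124 and 20 without JHOC9 IL-6 knockdown replicates b, d and e. Across all clusters the changes in the lines correlated at r = 0.24, which fell to 0.06 without JHOC9 IL-6 knockdown replicate b and to 0.03 without JHOC5 IL-6 knockdown replicate a, and was 0.0278 with array weights.

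A difference between the lines in the response to the IL-6 virus passed limma's test for 2 clusters, 1 in each direction. An unadjusted p under 0.05 was found for 4373 of the 65526 clusters, where chance alone would give a share of 0.05. The count of 2 was 0 without JHOC9 NT replicate a, b or d, JHOC5 NT replicate b, c, d or e, or JHOC5 IL-6 knockdown replicate c, and 1 without JHOC9 NT replicate c. It was 6 without JHOC9 IL-6 knockdown replicate b or e or JHOC5 IL-6 knockdown replicate a or b, 12 without JHOC5 NT replicate a, and 507 with array weights. Among the 87 shared falls, 69 were larger in JHOC5, and 1 of them passed the test of the difference.

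**Figure D2:**
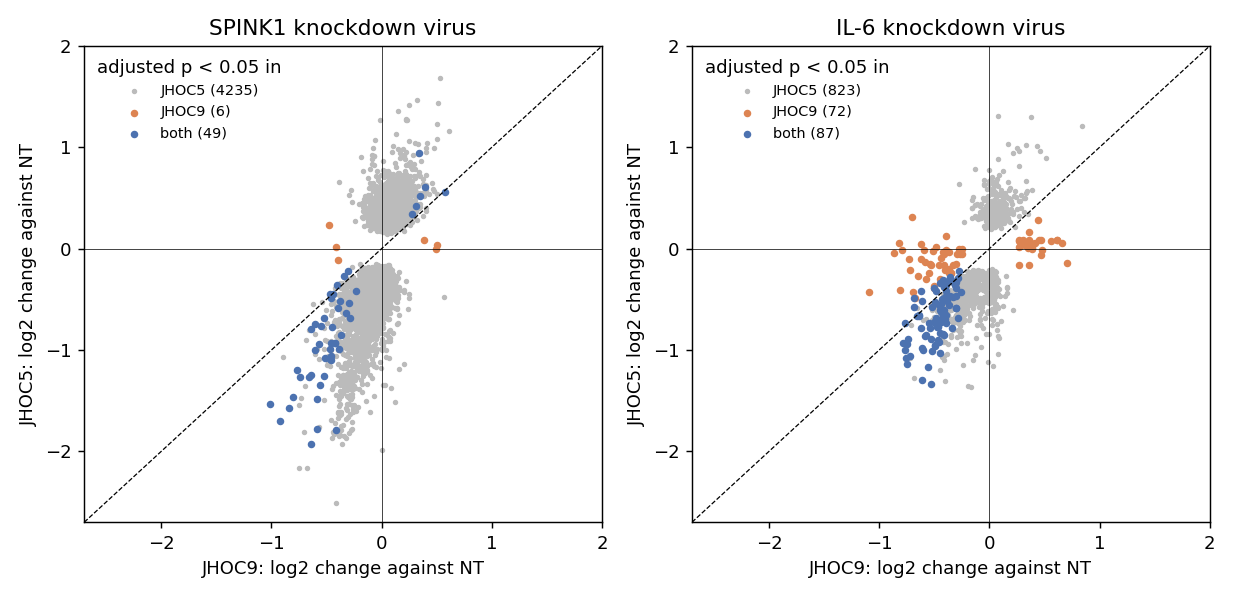
Log2 change against NT in JHOC9 (horizontal axis) and JHOC5 (vertical axis) for the SPINK1 virus (left) and the IL-6 virus (right). Each point is a transcript cluster with an adjusted p under 0.05 in JHOC5 alone (grey), JHOC9 alone (orange) or both lines (blue), and the dashed line marks equal change. The blue points number 49 with the SPINK1 virus and 87 with the IL-6 virus.

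The series sets both knockdowns side by side, which leads to the question of whether they changed the same transcripts within a line. In JHOC5, 176 clusters were lower and 104 higher with both viruses, against 24.1 and 7.62 for independent lists, and 53 went in opposite directions. Both comparisons use the same NT arrays. Unchanged groups simulated against those arrays shared 0 calls in each of 20 simulations, but such groups give almost no calls to share, so this value says little about the 280. With each virus set against its own part of the NT arrays, 20 splits gave between 49 and 109 shared calls, with a median of 89.5. The 280 shared calls were 170 without NT replicate d, 149 and 176 without IL-6 knockdown replicates a and b, and 780 with array weights. The observed r of the changes was 0.27, against a simulated 0.37 and a median of 0.12 over the splits. The covariance was 0.00689, against 0.00395 in the simulation, which drew unpaired arrays.

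In JHOC9, 1 cluster was lower with both viruses, against 0.0927 for independent lists, and none was higher with both. The r of the changes was 0.08, against 0.38 in the simulation and a median of -0.17 over the splits. The covariance was 9.99e-04, below the simulated 0.00397. The simulation drew unpaired arrays, while the SPINK1 comparison in JHOC9 was treated as paired, so its r and covariance may not be the right reference here. The splits shared between 0 and 1 calls. The overlap was 6 with the replicate block, 21 with array weights, 2 after cyclic loess and 0 with arrays centred on their median. It was 0 without NT replicate b, SPINK1 knockdown replicate b or c, or IL-6 knockdown replicate e, and 2 without NT replicate d or IL-6 knockdown replicate d.

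The knockdowns were also compared directly, as a difference of the knockdown means. The NT arrays still entered the estimate of the spread, except with the compared groups alone. With the replicate block they also entered the letter effects. In JHOC5, 3914 clusters differed, 1805 higher and 2109 lower with the SPINK1 virus than with the IL-6 virus. The count was 1966 with the compared groups alone and 1267 at a change of at least 1.5-fold, where 433 were higher and 834 lower. Array weights raised it to 8118, with 4159 higher and 3959 lower, and without IL-6 knockdown replicate c 1465 were higher and 1455 lower, so the excess of lower clusters depends on both. In JHOC9, 412 clusters differed, 332 higher and 80 lower with the SPINK1 virus. That count was 88 with the replicate block, 42 with JHOC9 arrays alone and 7489 with array weights, where 3061 were higher and 4428 lower, which turns the balance. It was 0 with the compared groups alone by limma, where 6623 clusters had an unadjusted p under 0.05. It was 101 and 115 without SPINK1 knockdown replicates a and b, and 272 and 115 without IL-6 knockdown replicates b and e. Without IL-6 knockdown replicate b, 149 were higher and 123 lower. Of the 43 clusters that the SPINK1 virus lowered in both lines, 25 in JHOC9 and 37 in JHOC5 were lower than with the IL-6 virus. Of the 87 that the IL-6 virus lowered in both lines, 64 in JHOC9 and 62 in JHOC5 were lower than with the SPINK1 virus. Both sets were chosen for low values on knockdown arrays that this comparison reuses, which favours such calls.

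The NT arrays of the lines were compared as a baseline. Between them, 19705 of the 65526 clusters differed, 11161 higher and 8544 lower in JHOC9. Of these, 6562 differed at least 1.5-fold, 3234 higher and 3328 lower. Cyclic loess normalization gave 8844 higher and 10129 lower clusters, so which direction held more clusters depends on the normalization. Line, serum content and any batch tied to the line cannot be told apart in this comparison.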

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

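The tests of the ratio between lines, of an equal effect in the lines and of a response to any virus were chosen after the result was seen, as was cyclic loess normalization.

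The response to the SPINK1 virus differed between the lines, with 813 clusters past the interaction test. Many more clusters changed in JHOC5 than in JHOC9. The model uses 1 spread per cluster for all groups, so a cluster has the same SE in both lines. A larger spread between JHOC9 arrays would also leave changes of about equal size. The median ratio of the JHOC9 to the JHOC5 change was instead 0.207 (0.168 to 0.231 without single arrays), which argues against it. Equal effects simulated with the shared spread gave 0.949. That simulation took the JHOC5 estimates as true, so it does not model in full that these clusters were chosen for large JHOC5 changes. An array-wide trend with signal level is also argued against, since cyclic loess left 3975 clusters in JHOC5, and 2342 to 4399 without single arrays. A weaker knockdown in JHOC9, a different response of the lines, and serum or batch stay open, as untested.

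Regrouping the arrays of both lines tests for no effect at all, not for an equal effect in the lines, so it does not decide about the difference: 3 of 100 drawn splits, the real one included, gave as many clusters, and the other such draws, with 1640 in the highest, kept all JHOC5 knockdown arrays in place. An equal effect in the lines was therefore tested with the average knockdown effect of both lines subtracted first. Then 1 of the 100 regroupings, the real one, reached 813, and the highest other gave 6. This argues against an equal effect only if the arrays are interchangeable. The draws were not limited to those that part same-letter arrays, and the SPINK1 comparison in JHOC9 was treated as paired.

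The response to the IL-6 virus also differed between the lines by the interaction test, for 2 clusters. With the average effect subtracted, 5 of 100 regroupings gave as many, with 643 in the highest other, so an equal effect in the lines is not excluded for this count. That highest regrouping calls many times the real count, and the cause of this was not tested. Without the subtraction, which does not test the difference, 5 of 100 splits gave as many, with 364 in the highest other.

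For the SPINK1 virus in JHOC5, 1 of 56 splits reached 4284 clusters (highest other 37), and for the IL-6 virus in JHOC5, 1 of 56 reached 910 (highest other 10). These shares are under 0.05 only if the arrays are interchangeable. Same-letter knockdown and NT arrays correlated at 0.27, 0.06 and 0.37 for SPINK1 and at 0.52, -0.00159 and 0.40 for IL-6. If arrays pair by letter, 8 splits part as many pairs, with a highest other of 9 and 0, and are too few for a share under 0.05. Chance is therefore not excluded for paired arrays. For the SPINK1 virus in JHOC9, where the arrays were treated as paired by letter, the 8 splits that part as many pairs are too few for a share under 0.05, with 55 against a highest other of 0. Of all 56 splits there, 1 reached 55, and the highest other, 21, came from a split that parts fewer pairs. For the IL-6 virus in JHOC9, 2 of 56 splits reached 159. The other of these gave 357 clusters by exchanging IL-6 knockdown replicate b for NT replicate e, which puts both arrays lettered e together. Same-letter arrays of this comparison correlated at 0.31, -0.04 and 0.48 for letters b, d and e. Whether a structure by letter caused the 357 was not tested. A split so far above the real one leaves in doubt whether the arrays are interchangeable, so the share is not taken to decide about chance. The blocked count for that comparison was 176. For the knockdowns against each other, 10 splits are too few for a share under 0.05. The real split was 1 of 10 in each line, with 412 against a highest other of 4 in JHOC9 and 3914 against 2 in JHOC5. For the NT arrays, 1 of 100 drawn splits reached 19705, with 1 in the highest other.

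The same clusters fell in both lines with the same virus, 43 with SPINK1 and 87 with IL-6. A response to any knockdown virus is argued against for these clusters as a set, since the other virus moved them by a median of at most 0.215 of the change (at most 0.301 without single arrays). They were chosen for their falls with 1 virus, which lowers this ratio, and a median leaves room for a common response in some of them. Of the 43, 25 in JHOC9 and 37 in JHOC5 were called lower than with the other virus, and of the 87, 64 and 62. The same choice favours these calls, so they add no independent evidence. Silencing of other transcripts by the hairpin itself and loss of the target cannot be told apart for these clusters, since the design has 1 hairpin per gene. Clusters of identical values counted more than once are argued against for these falls. Counting such clusters once left 100% of them, 43 with SPINK1 and 87 with IL-6. The same step took the rises shared by both viruses in JHOC5 from 104 to 99, so it could remove shared calls. Clusters that share some probes without having identical values were not tested and stay open.

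The SPINK1 virus in JHOC5 and the IL-6 virus in JHOC9 share no array, yet their changes correlated at r = 0.26 over clusters (0.15 to 0.31 without single arrays, lowest without JHOC9 IL-6 knockdown replicate b). Between them, 43 clusters fell in both, against 5.10 for independent lists, and 4 were called in opposite directions. Both lists of calls use the same spread per cluster. An array-wide trend with signal level is argued against, since cyclic loess left r at 0.247. An axis along which arrays of one group vary stays open: given the first 2 principal components of the deviations within groups, the partial r was 0.198, which is 0.760 of r. The bound set before the test was 0.75. Leaving out single arrays, a condition added after that value was seen, moved the share from 0.592 to 0.931, so the test does not decide. The reverse pair, the SPINK1 virus in JHOC9 and the IL-6 virus in JHOC5, shares no array either, and its changes correlated at r = 0.065. In that pair 7 clusters fell and 4 rose in both, against 0.439 and 0.0391 for independent lists, and 2 went in opposite directions. The correlation was thus weaker in the reverse pair, and a response common to both knockdowns is untested beyond this.

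For cluster TC07000113.hg.1 in JHOC5 NT, replicate a stood apart, at a log2 signal of 3.42 against 3.22 to 3.26 in the others (gap over range 0.807). It was 1 of 34 groups of 5 tested, and chance marks about 1 in 20.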

How the results depend on the processing

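Every named cluster kept its sign in every setting run. Calls of 9 of the 16 named clusters held in every setting, and the others were lost in 2 to 14 settings, the stricter thresholds not counted. TC20000928.hg.1 (1.49-fold, limma adjusted p = 0.0134) and TC15002759.hg.1 (1.41-fold, 0.0289) miss both stricter thresholds. An adjusted p under 0.01 is also missed by TC07000113.hg.1 (0.0117), TC17000279.hg.1 (0.0473) and TC15001529.hg.1 (0.0349). Cyclic loess, repeated clusters counted once and the letter block for the NT contrast were chosen after seeing the data. The dim filter, the other table, trend and robust eBayes, and repeated clusters counted once left all 9 counts and 4 overlaps within 1.5 times. For the rest the cause was not tested unless given. Values follow the order JHOC9 SPINK1, JHOC5 SPINK1, JHOC9 IL-6 and JHOC5 IL-6 against NT, then the SPINK1 and IL-6 line differences, then the direct comparison in JHOC9 and JHOC5, then NT.

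With fewer arrays in the fit, fewer degrees of freedom remain, and the spread is no longer shared with the groups left out. Which of these moved the counts was not tested. The JHOC5 SPINK1 count stayed at 4236 with the compared groups alone. The compared groups alone gave 12, 2 and 447 for JHOC9 SPINK1, JHOC9 IL-6 and JHOC5 IL-6, 0 for the IL-6 line difference (limma; 4216 at an unadjusted p under 0.05), and 0 and 1966 for the direct comparisons (6623 unadjusted in JHOC9). Arrays of 1 line gave 19, 33 and 42 for JHOC9 SPINK1, JHOC9 IL-6 and the JHOC9 direct comparison. Arrays centred on their median gave 29 for JHOC9 SPINK1, 27 for its overlap between lines and 0 for the JHOC9 overlap of the viruses. Cyclic loess gave 36 and, for the JHOC9 overlap, 2. The IL-6 line difference was 0 under median centring, cyclic loess and quantile normalization of the linear signals (4308, 4600 and 4599 unadjusted) and 5 with the centred values quantile normalized again.

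Array weights gave 2948, 7047 and 3369 for JHOC9 SPINK1, JHOC5 SPINK1 and JHOC5 IL-6, 3621 and 507 for the line differences, 7489 and 8118 for the direct comparisons, and overlaps of 796 for SPINK1 between lines, 21 in JHOC9 and 780 in JHOC5. These weights ran from 0.319 to 6.46, the highest on JHOC9 SPINK1 knockdown replicate b. In the JHOC9 SPINK1 and JHOC5 IL-6 knockdown groups the weighted mean rests mostly on replicate b. At an adjusted p under 0.05 and at least 1.5-fold, the counts were 13, 1031, 37, 206, 477, 1, 82, 1267 and 6562, and the overlaps 13 and 15 between lines for SPINK1 and IL-6, 0 in JHOC9 and 27 in JHOC5. At an adjusted p under 0.01 the counts before NT were 24, 2553, 31, 401, 351, 0, 97 and 2386, and the overlaps 23, 29, 0 and 107. With NT arrays split, which also leaves fewer NT arrays for each virus, the overlap of the viruses had a median of 0 in JHOC9 and 89.5 in JHOC5.

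The replicate block gave 120 for JHOC9 SPINK1, 7 for the IL-6 line difference, 88 for the JHOC9 direct comparison, and overlaps of 90 for SPINK1 between lines and 6 in JHOC9, and moved no other count by over 1.5 times. The titles tie the letters to experiments for the NT arrays, and whether knockdown arrays of a letter belong to the same experiment is not stated. An array correlated best with its own letter in 2 of 3 IL-6 knockdown arrays in each line, 1 of 3 JHOC5 SPINK1 knockdown arrays and 2 of 3 JHOC9 SPINK1 knockdown arrays.

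Without single arrays the counts ranged from 25 to 63, 2624 to 4243, 24 to 255, 510 to 892, 442 to 1100, 0 to 12, 101 to 483, 2727 to 3649 and 17961 to 19257. The overlaps ranged from 23 to 58 (SPINK1) and 20 to 124 (IL-6) between lines, 0 to 2 in JHOC9 and 149 to 265 in JHOC5. Not run, because the files do not pair IDs with names: the mean of a gene's probe sets, gene lists, and the levels of SPINK1 and IL-6. Of the clusters called against NT, rises and falls together, 86.6% to 98.2% lay in the upper part of the signal range split at its median. Rises with the IL-6 virus in JHOC9 differed from this. With clusters put into 10 equal groups by signal, the 5 lowest groups held 3, 3, 5, 2 and 3 of its 27 rises. Recovery of changes by signal level was not tested.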

Other observations

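The test on neighbouring IDs was chosen after the result was seen. Clusters were grouped by the chromosome code in their IDs to describe the NT arrays of the lines. By camera with its preset correlation, 3 of 25 codes passed. Code 18 was shifted towards lower signal in JHOC9, with 67 clusters higher and 251 lower (adjusted p = 8.63e-05). Code 19 was shifted higher, with 908 higher and 185 lower (adjusted p = 3.06e-05), and code X lower, with 309 higher and 507 lower (adjusted p = 0.0410). With an estimated correlation none of the 3 passed, with adjusted p = 0.441 for code 18 and 0.931 for codes 19 and X. Among clusters above the array median in at least 3 arrays, an alternative added after seeing the data, codes 18, X and 6 passed with an estimated correlation (adjusted p = 2.23e-04, 0.00244 and 0.0354). Code 19 did not, with 0.707. No code passed by camera in any of the 4 knockdown comparisons against NT, where 1 code had an unadjusted p under 0.05, for the IL-6 virus in JHOC5, and 0 in the others.

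Copy number differences between the cell lines are a candidate explanation for the shift of code 18. They would make runs of neighbouring clusters differ together, so bright distinct clusters were put in ID order into 848 windows of 40. In the NT comparison the SD of the window medians was 2.76 times its mean after shuffling the IDs. Of the 848 windows, 18 lay beyond the most extreme of 1000 shuffles, 17 of them lower in JHOC9, and 5 of the 11 windows with code 18 were among them. The knockdown comparisons gave 1.19 to 1.72 times, above the shuffled range as well, so neighbouring clusters also move together for other reasons, such as shared transcripts or regulation, and the test does not separate these from copy number.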
